A study of Halobacterium salinarum NRC-1 with 49 samples.

How the data were processed

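RNA abundance was measured in Halobacterium salinarum, a salt-loving archaeon, before and after copper(II) sulfate was added to bioreactor cultures. Per the labels, the copper concentration was 0.85 mM and each sample was hybridised together with a common reference RNA from an unperturbed batch culture. Each of the 49 samples was hybridised on 2 spotted 2-colour arrays with the dyes swapped, which gave 98 arrays. The dye that carried the sample was taken from the name under which each array was deposited, and all log ratios were turned to sample over reference.

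The deposited scanner files hold the mean intensity of each spot and the median intensity of its local background for both dyes, per the file headers, with no normalization recorded. They also hold a confidence score per spot and dye, per the file headers, whose calculation is not given in the sources used here. The deposited table of processed values holds 1 value per probe and sample on a log10 scale, and the software behind it is not given in the sources used here. Its scale and direction were found by setting it against the scanner values: the median slope on log2(sample/reference) was 0.294 over the 33 samples outside the 2 courses described below, where a log10 ratio gives 0.301. Medians of the table's columns lay between -0.026 and 0.0505, and how the authors centred them stays unknown. No column of the table went unmapped to a sample.

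The scanner files carry no probe names. The pairing of spots with probes was therefore worked out from the regular print layout, by setting scanner values against the authors' table. Of the 10752 spots per array, 9600 belonged to 2400 probes with 4 spots each, and 1152 spots lay outside the table. Across samples, the median correlation of a probe with its assigned table line was 0.785, against -0.00155 for all other lines. The assigned line ranked first among 2400 for 39.2% of probes and within the first 24 for 72.5%, where chance gives 1%. A probe with little variation can therefore be paired less surely than a variable one. Scanner values were not independent of the authors' table in this step.

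Background was corrected with normexp (offset 50) and arrays were normalized by loess within each array, with spots outside the table given no weight in the loess curve. The spots of a probe were averaged, and the 2 dye orientations of a sample were averaged to 1 log2 ratio. Computations used R 4.3.3 with limma 3.58.1, and plots used Python 3.11.15 with matplotlib 3.10.9. No depth can be given for arrays, and their number limits the precision. Between 42.3% and 99.99% of probe spots per array and dye were brighter than their background. After background correction the 2 dye orientations of a sample correlated poorly in the later courses: the median r per course was 0.518 and 0.346 for NRC-1 replicates 1 and 2, -0.00886 and -0.322 for sets 1 and 2 of NRC-1 replicate 3, and -0.361 and -0.0136 for Dura3 replicates 1 and 2. With no background subtraction the values were higher, in the same order 0.618, 0.842, 0.361, -0.0963, 0.184 and 0.217, so the correction lowered them. A dye effect cancels in the mean of both orientations, but with low values each sample mean rests on orientations that differ widely. No pair of arrays with the same dye orientation correlated below -0.3, and the lowest r was -0.133.

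Samples were grouped by strain, course and time from the labels. Each course gave 4 values per probe: before copper, 0 min, early (the mean of 5, 10 and 20 min) and late (the mean of 40, 80 and 160 min). Neighbouring times of a course come from the same culture, so their mean counted as 1 replicate. limma was fitted to the 24 values of each probe with a mean per strain and phase and no course term, with Benjamini-Hochberg adjustment over 2400 probes in each comparison, and probes with an adjusted p under 0.05 were called. All tests were two-sided. The SE and p of a change come from this fit, which pools the spread over all groups of strain and phase. The SD printed beside an SE is that of the courses' own changes, a different spread. The labels name separate replicates but do not say that sets 1 and 2 of replicate 3 came from separate cultures, so part of the spread between courses may be technical. Samples of a course deviated together from their group means: the correlation between phases ranged from 0.492 to 0.888 in the 4 NRC-1 courses and from 0.0924 to 0.395 in the Dura3 courses, whose deviations mirror each other because there are only 2. The samples of a course follow the same bioreactor culture, per the labels, so the course pairs them, and fits with the course as a block are given beside the results they change.

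The fit was tested on simulated data for 2400 probes, with changes of 0.5, 1 and 2 placed in 67, 67 and 66 probes per comparison. For the NRC-1 early comparison it recovered 73.1% of changes of 0.5, 95.5% of changes of 1 and 98.5% of changes of 2 on the log2 scale. For the Dura3 early comparison the shares were 52.2%, 89.6% and 97.0%, for the strain comparison before copper 56.7%, 91.0% and 98.5%, and for the early difference between the strains' responses 38.8%, 80.6% and 100%. False calls were 11 of 189, 12 of 171, 6 of 170 and 4 of 150. Benjamini-Hochberg adjustment is stricter where few probes change, and far fewer probes were called in the real data. The simulated values of a probe were also drawn independently, whereas the real phases of a course deviated together. Neither the recovered shares nor the false calls therefore carry over to the real data.

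The rule for named probes, fixed before the data were examined, took the largest rises and falls among called probes that moved the same way in every course. The files do not pair probe IDs with gene names. The annotation table at hand, with 2597 genes of strain 91-R6, held 0 of the probe IDs. The 28 gene lists fixed before the data were examined could therefore not be tested. Nor could the probe for the ura3 gene be looked up as a check of the strain labels. Of the called probes, only the 2 largest rises and the 2 falls of NRC-1 early are given by ID, fewer than the rule would name. The alternatives covered background, normalization, dim probes, dye orientation, spot summary, the authors' table, the phases, the course block and leaving out each course. Others were added after the data were seen and are named as such in the closing section. The spots outside the table were tested separately.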

Results

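The series followed the transcriptome of Halobacterium salinarum through a shift to 0.85 mM copper, with the samples taken before copper as controls. Strain NRC-1 was followed in 4 courses with 33 samples, and a strain labelled NRC-1 Dura3, called Dura3 here, in 2 courses with 16 samples. The other strain, labelled NRC-1 alone, is called NRC-1. Courses ran from before copper through 0, 5, 10, 20, 40, 80 and 160 min, and NRC-1 replicate 2 had a further sample at 320 min. The sample before copper was taken at -1 min in NRC-1 replicates 1 and 2 and at -30 min in the other 4 courses. NRC-1 replicates 1 and 2 had a median r of 0.827 with each other over probes at matched times, but only 0.0172 to 0.102 with the sets of NRC-1 replicate 3. Sets 1 and 2 of NRC-1 replicate 3 had a median r of 0.371 with each other, less than the 0.394 to 0.573 of either set with the Dura3 courses, while the Dura3 courses had only 0.104 to 0.142 with NRC-1 replicates 1 and 2. These are scanner values, and the labels of 2 of the -30 min courses conflict, as described next. In the authors' values the sets had 0.528 with each other, the Dura3 courses 0.626 with each other, and either set 0.411 to 0.563 with the Dura3 courses. NRC-1 replicates 1 and 2 had 0.659 with each other there and 0.00625 to 0.167 with the other courses. In both kinds of values NRC-1 replicates 1 and 2, sampled at -1 min, parted from the 4 courses sampled at -30 min, which bears on every comparison of strains. Between these groups of courses the matched times leave out the sample before copper. The values therefore do not show that its timing parted the courses, and it cannot be told apart from other differences between the groups. Likeness by strain among the -30 min courses depended on the values and labels used.

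The labels of 2 courses conflicted between the scanner files and the authors' table. All 16 samples of the courses labelled NRC-1 replicate 3 set 1 and Dura3 replicate 1 matched best the table column of the other course at the same time, with r from 0.772 to 0.953. Their r with the column of their own label was 0.427 to 0.631. Of the other 33 samples, 28 matched best their own column and 32 a column of their own course. Their median r to their own column was 0.881, with a lowest r of 0.138 for NRC-1 replicate 1 at 5 min. NRC-1 replicate 1 at 160 min matched best replicate 2 at 320 min (r = 0.823, against 0.691 with its own column). NRC-1 replicate 2 at 5, 40 and 160 min matched best other times of its course, at 160 min with 0.933 against 0.857. Times within these courses were therefore matched less surely than the courses. All courses are used here as the scanner files are labelled. Every statement on a strain rests on labels that the table contradicts for the 2 courses of conflicting label.

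**Figure D1:**
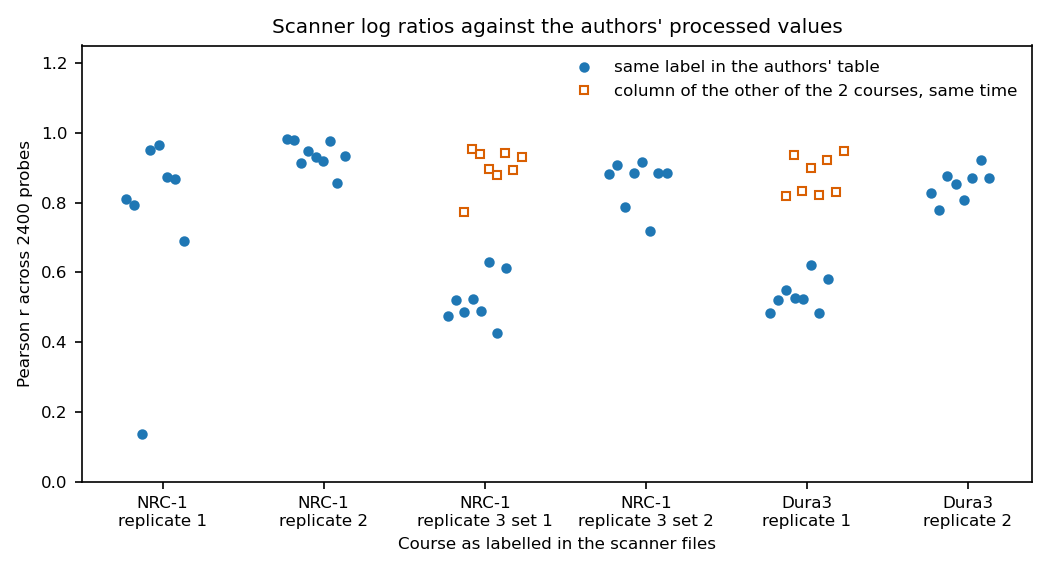
Pearson r across 2400 probes between each sample's scanner log2 ratios without background subtraction and the authors' processed values, by course as labelled in the scanner files. Filled circles use the column with the same label and open squares, drawn for 2 courses, the column of the other of those courses at the same time; the squares lie at 0.772 to 0.953 and the circles of those courses at 0.427 to 0.631.

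The first question was which transcripts changed in NRC-1 within 5 to 20 min of copper. Probe HO02O14 rose most, by 2.05 on the log2 scale (4.15-fold, SE 0.10, SD 0.18 between courses, n = 4), with course values of 1.88 to 2.29 and an adjusted p of 2.34e-11 in limma. Probe HO06E13 rose by 0.86 (1.82-fold, SE 0.12, SD 0.10, n = 4, adjusted p = 0.00112). Probe HO07K03 fell by 0.64 (SE 0.09, SD 0.31, n = 4, adjusted p = 0.00112), with course values from -1.00 to -0.36, and probe HO03F02 fell by 0.33 (SE 0.05, SD 0.08, n = 4, adjusted p = 0.00234). In all, limma called 7 of 2400 probes, 5 higher and 2 lower, and each moved the same way in 4 of 4 courses. The 3 risen probes not given by ID rose by 0.43 to 0.54. The one that rose by 0.54 lies, by its ID, 2 rows from HO06E13 in the plate. Changes of probes at that distance correlated in general, as described under Other observations, so these calls may not be independent. In the layout check its own table line correlated at 0.789 and the next best line at 0.772. At an unadjusted p under 0.05 there were 61 probes, where 120 are expected by chance. This fit has no course term, although the samples of a course deviate together. The median half-width of its 95% interval was 0.240, against 0.149 with the replicate block. A count under chance can therefore not be read as an absence of changes. With the replicate block the count was 11, 9 higher and 2 lower, and included all 7. The count was 3 without set 2 and 4 without set 1 of NRC-1 replicate 3, and 2 with both courses of conflicting label left out. Within the courses sampled at -1 min it was 3 and within those sampled at -30 min 11, and HO07K03 did not pass within the latter (adjusted p = 0.328, over a range across alternatives of 7.92e-06 to 0.328). HO03F02 passed in 19 of 27 alternatives, over adjusted p from 9.60e-05 to 0.538, and did not pass within either kind of course or in the authors' values. HO06E13 passed in 26, all but the one without the courses of conflicting label (adjusted p = 0.282, over a range of 5.37e-07 to 0.282).

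From 40 to 160 min, HO02O14 stayed raised in NRC-1 by 1.97 (3.91-fold, SE 0.10, SD 0.16, n = 4, adjusted p = 5.16e-11). HO06E13 was still 0.74 above its level before copper (SE 0.12, SD 0.15, n = 4, adjusted p = 0.00943). A further risen probe was up by 0.36 (SE 0.07, adjusted p = 0.0468). These were the 3 probes called by limma, all higher in 4 of 4 courses, with 61 at an unadjusted p under 0.05. The falls of the early phase did not pass late: HO07K03 stood at -0.24 (adjusted p = 1.00) and HO03F02 at -0.10 (adjusted p = 1.00). With the replicate block 16 probes were called, 14 higher and 2 lower. HO06E13 passed in 13 of 27 alternatives, over adjusted p from 7.63e-06 to 1.00, and did not pass in the authors' values (0.66, adjusted p = 0.190). The labels do not say that sets 1 and 2 of NRC-1 replicate 3 were separate cultures, and with the sets averaged the count was 1. It was also 1 with the 2 courses of conflicting label exchanged or left out, without NRC-1 replicate 2, without set 1 of NRC-1 replicate 3, and without either Dura3 course, whose spread the fit shares.

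The time courses differed in shape, as described by means over the 4 NRC-1 courses without a test between times. HO02O14 was 0.03 ± 0.15 (SD) from its level before copper at 0 min, 1.72 ± 0.26 above it at 5 min, 2.30 ± 0.36 at 20 min and 1.52 ± 0.54 at 160 min. At 320 min, with 1 sample and no replicate, it was 1.27 above, against 1.58 at 160 min and 2.66 at 20 min in the same course. These means join courses of unlike shape. The log2 ratio of HO02O14 went from 1.39 and 1.21 at 5 min to 2.53 and 2.28 at 20 min in NRC-1 replicates 1 and 2. In sets 1 and 2 of replicate 3 it went from 1.70 and 1.93 at 5 min to 1.82 and 1.92 at 20 min. The 5 min value of replicate 1 is in doubt. That sample matched the authors' 10 min column of its course (r = 0.831) better than its own (0.138), and the authors' ratio of HO02O14 was -0.04 there. In the authors' values the mean changes at 5 min were 1.26 ± 0.86 for HO02O14 and 0.49 ± 0.58 for HO06E13. HO06E13 was 0.72 ± 0.22 above at 5 min, 1.11 ± 0.35 at 20 min and 0.38 ± 0.20 at 160 min. The third probe called in both phases came later: it was 0.08 ± 0.15 above at 5 min, 0.82 ± 0.19 at 20 min, 0.82 ± 0.15 at 40 min and -0.15 ± 0.09 at 160 min. For this probe the layout check gave r = 0.939 with its own table line and 0.914 with the next best. The mean of HO07K03 was lowest at 10 min, at -0.72 ± 0.35. It stood at -0.57 ± 0.13 at 5 min, -0.64 ± 0.44 at 20 min, -0.32 ± 0.22 at 40 min and -0.18 ± 0.05 at 160 min. By course, HO07K03 was lowest at 20 min in replicate 1, at 10 min in replicate 2 and at 5 min in both sets of replicate 3. The mean of HO03F02 was also lowest at 10 min, at -0.38 ± 0.09, and stood at -0.12 ± 0.07 at 40 min. By course, HO03F02 was lowest at 20 min in replicate 1, at 5 min in set 1 of replicate 3 and at 10 min in the others.

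**Figure D2:**
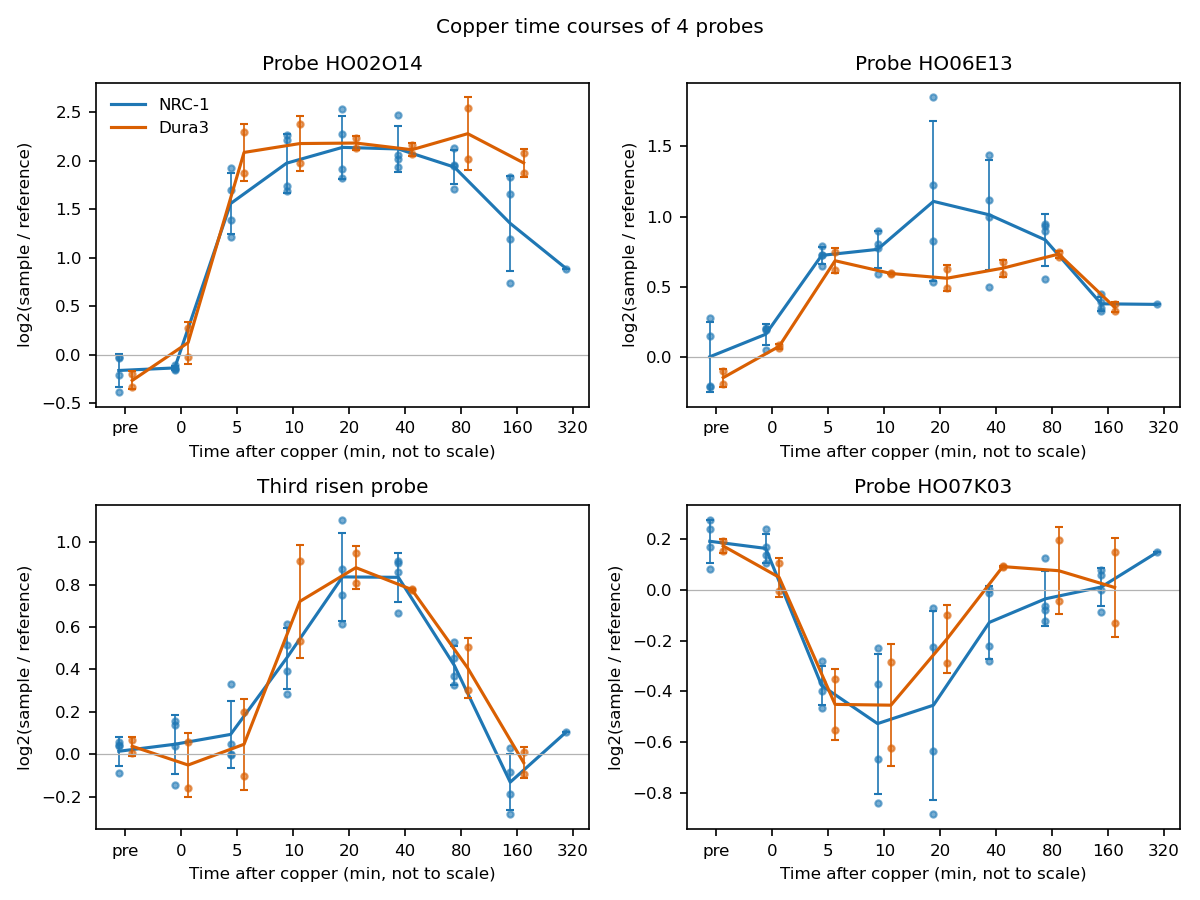
Log2(sample/reference) of 4 probes before copper and at 0 to 320 min, with time on an axis that is not to scale. Points are courses (n = 4 for NRC-1, n = 2 for Dura3, n = 1 at 320 min), lines join means and bars show the SD. Over the NRC-1 courses, the mean of HO02O14 was 1.72 above its level before copper at 5 min. That of the third risen probe was 0.08 above at 5 min and 0.82 at 20 min. The mean of HO07K03 was lowest at 10 min, but the time of its lowest value differed between courses. In the authors' values the mean of HO02O14 was 1.26 above at 5 min. For NRC-1 replicate 1 at 5 min the scanner and authors' values correlated at only 0.138.

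Dura3 was given the same copper treatment in 2 courses. HO02O14 rose there by 2.41 early (5.33-fold, SE 0.14, SD 0.08, n = 2, adjusted p = 6.60e-10 in limma) and 2.39 late (5.24-fold, SE 0.14, SD 0.29, n = 2, adjusted p = 7.96e-10). The later-rising probe of NRC-1 rose by 0.51 early (SE 0.10, adjusted p = 0.0440), and another probe by 0.90 (SE 0.16, adjusted p = 0.0314), whose NRC-1 early value was 0.48 (adjusted p = 0.140). By their IDs these 2 probes lie 2 rows apart in the plate. HO06E13 had early and late values of 0.76 and 0.72 (adjusted p = 0.145 and 0.177), which passed with the replicate block (adjusted p = 0.00245 and 0.00321, over ranges across alternatives of 0.00112 to 1.00 and 0.00244 to 1.00). HO07K03 had an early value of -0.54 (adjusted p = 0.249) and with the replicate block an adjusted p of 0.0420, over a range of 0.0131 to 1.00. HO03F02 had -0.27 (adjusted p = 0.315, and 0.0969 with the replicate block) and passed in 2 of 24 alternatives, over a range of 0.0373 to 1.00. limma called 3 probes early, all higher, and 1 late, higher, with 96 and 115 at an unadjusted p under 0.05, and with the replicate block 10 and 20. All 7 probes called early in NRC-1 had the same sign in Dura3, and 2 of them were called there. Early, the authors' values gave 1 probe, as did exchanging or leaving out the courses of conflicting label, leaving out NRC-1 replicate 1 gave 5, and leaving out either Dura3 course, NRC-1 replicate 2 or set 1 of NRC-1 replicate 3 gave 1. Late, leaving out Dura3 replicate 2 gave 7.

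The difference between the strains' responses was tested directly. HO02O14 rose 0.36 more in Dura3 than in NRC-1 early (95% interval 0.01 to 0.71, adjusted p = 1.00) and 0.42 more late (0.08 to 0.77, adjusted p = 1.00), so neither difference passed. With the 2 courses of conflicting label exchanged the early difference was -0.018, so its size depended on these labels. It was -0.16 with no background subtraction as well, which also changes the background setting. The late difference was 0.31 and 0.030 in these fits. In the authors' values the differences were -0.35 and -0.25. limma called 0 probes early and 0 late, with 37 and 79 at an unadjusted p under 0.05, and 0 and 0 with the replicate block (98 and 161 unadjusted). Without Dura3 replicate 2 there were 4 late. Half-widths of the 95% interval for a single probe had a median of 0.42 over probes, and of 0.26 with the replicate block. Across the 2400 probes the changes of the strains correlated at r = 0.525 early (Spearman 0.310) and 0.345 late (0.206). Probes are not independent replicates, and no p is given. Without HO02O14 the values were 0.470 and 0.270. Over the 8 pairs of an NRC-1 and a Dura3 course r ranged from 0.0343 to 0.479 early and 0.0725 to 0.275 late. In the authors' values r was 0.0880 early (Spearman -0.146) and -0.00781 late (Spearman -0.169), so the likeness of the strains beyond the named probes did not hold there.

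Before copper, the strains differed at 1 probe in limma. It read -1.47 in Dura3 (n = 2) and -0.04 ± 0.27 (SD, n = 4) in NRC-1, a difference of -1.43 (SE 0.23, adjusted p = 0.0158), and 169 probes passed an unadjusted p under 0.05. The probe was dim, with 9.88% of probes dimmer, and its own table line ranked only 5 for it in the layout check. With no background subtraction its difference was -0.43 (adjusted p = 0.737) and 0 probes were called, and without the dim 25% of probes, which hold it, also 0. In the authors' values its difference was -0.07 (adjusted p = 0.874, over a range across alternatives of 0.000926 to 0.874), and 2 other probes were called there, by -1.32 and -0.80 (adjusted p = 0.0295 and 0.00667). The count was 0 with the course as a random block (adjusted p of the probe 0.149) and 0 against NRC-1 replicate 3 alone. It was 11 without set 1 of NRC-1 replicate 3, 4 without Dura3 replicate 2, and 0 without any other single course. With the 2 courses of conflicting label exchanged it was 6, without the probe called here, and with both left out 6, with that probe among them.

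The sample at 0 min was compared with the one before copper. In NRC-1 limma called 0 probes, with 60 at an unadjusted p under 0.05, and 0 with the replicate block (218 unadjusted). In Dura3 it called 5, of which 2 were higher and 3 lower, with 163 unadjusted, and 37 with the replicate block. Their changes lay between 0.53 and 1.15 in size, and all 5 were among the dimmest 17.9% of probes. With no background subtraction 0 were called (14 unadjusted), and in the authors' values 0 (3 unadjusted). With the 2 courses of conflicting label exchanged the count was 0, with both left out 1 and with the sets of NRC-1 replicate 3 averaged 1. It was 9 without Dura3 replicate 2 and 0 or 1 without any other single course. HO02O14 stood at 0.39 in Dura3 at 0 min (SE 0.14, adjusted p = 0.324).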

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

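The tests on the labels of the 2 courses, and that on background in the Dura3 0 min calls, were chosen only after the result was seen.

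Among 29 groups of 4 samples tested for a sample far from the others, 1 stood out, and chance gives about 1 in 20 groups. The late change of HO06E13 was 0.97 in the course labelled NRC-1 replicate 3 set 1, while the other 3 NRC-1 courses lay between 0.65 and 0.68. No explanation was tested for it.

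In 2 courses the scanner files and the authors' table contradict each other. Poor arrays or different processing would leave the samples weakly correlated with every column, but the lowest r with the other course's column at the same time was 0.772. An exchange of the 2 courses' labels in 1 of the deposits is consistent with 16 of 16 samples matching the other course. As to which deposit, the difference Dura3 replicate 1 minus NRC-1 replicate 3 set 1 was set against the difference of the other Dura3 and NRC-1 replicate 3 courses. In the scanner files it went against the latter (r = -0.336 across probes, -0.394 with no background subtraction), the sign that wrong labels on the scanner files would give. In the table it went with it (0.451). Since the samples match crosswise between the deposits, this opposite sign follows from the first and is no separate support. Which deposit is wrong stays open, since both Dura3 courses and the disputed NRC-1 course are labelled set 1 and the other NRC-1 course set 2, so the second difference is also one between sets, and it rests on those 2 courses being labelled correctly.

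The 5 probes called at 0 min in Dura3 may come from the background correction of dim spots: with no background subtraction 0 were called, and their median size of change was 0.75 with the correction, 0.18 without it and 0.24 in the authors' values. Time or handling between -30 and 0 min, shared with NRC-1 replicate 3, stays open. With background correction the 0 min changes correlated at r = 0.181 across probes. This was little above the 0.129 with NRC-1 replicates 1 and 2, which were sampled at -1 min. With no background subtraction r with NRC-1 replicate 3 was 0.343, and no matching value was computed for replicates 1 and 2. A response to copper within the sampling time at 0 min was not tested and stays open.

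All 35 splits of the 8 NRC-1 values into groups of 4 were counted, the real one included. For the early comparison, 2 of 35 splits, the real one and 1 other, gave at least the 7 probes of the real one, and the other gave 1002. Late, 2 of 35, again the real one and 1 other, gave at least the 3 of the real one, and the other gave 817. Over all splits chance could therefore not be excluded by this count for the early and late comparisons. At 0 min the real split gave 0, so 35 of 35 splits gave as many whatever the data, and the count says nothing there (highest other 937). The splits with 1002, 817 and 937 probes set NRC-1 replicates 1 and 2 against the sets of replicate 3, a structure of the samples. Among the 8 splits that part all 4 pairs of a course, the real one was the highest, with 7 against 0 early and 3 against 0 late, and 8 splits are too few for a share under 0.05. With the replicate block, the counts were 11, 16 and 0.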

How the results depend on the processing

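The exchange of the 2 courses with conflicting labels, leaving both out, leaving out the 5 min sample of NRC-1 replicate 1, spot confidence, scaling, array weights and the random block for the strain comparison were chosen only after the data were seen. HO02O14 passed in all 27 alternatives in NRC-1 (early 1.77 to 2.19, late 1.70 to 2.04) and all 24 in Dura3 (early 1.46 to 2.51, late 1.58 to 2.64). The 0 min comparison in NRC-1 stayed at 0 in 26 alternatives, the early difference between strains at 0 in 25, and the 320 min value lay between 0.86 and 1.47 in 8. loess with Aquantile leaves log ratios as they are, so it tests nothing and is not counted among the alternatives. The gene lists and the ura3 probe were not run, for lack of gene names. Arrays with spots close to background limit dim probes. Where the cause of a change is not given by fewer samples or probes, the cause was not tested.

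Counts below are of called probes. With no background subtraction Dura3 at 0 min gave 0, the strain comparison before copper 0, and the late correlation of the strains was 0.427. With median centring NRC-1 late gave 1, Dura3 at 0 min 0 and the strain comparison 2 (1 higher). Without the dim 25% of probes Dura3 at 0 min gave 0, the strain comparison 0 and the late correlation was 0.577. In the authors' values NRC-1 late gave 1, Dura3 early 1, Dura3 at 0 min 0, the strain comparison 2, the correlations were 0.0880 and -0.00781, HO07K03 stood at 0.013 in Dura3 late, and the strain differences of HO02O14 were -0.35 and -0.25. With only the arrays that carry the sample in the shorter-wavelength Alexa dye NRC-1 gave 3 early and 1 late, Dura3 1 early and 0 at 0 min, the strain comparison 3, and the correlations were 0.283 and 0.213. With only those that carry it in the longer-wavelength dye NRC-1 early gave 3, Dura3 at 0 min 0, the strain comparison 4, and the early correlation was 0.360. With sets 1 and 2 averaged NRC-1 late gave 1 and Dura3 at 0 min 1.

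With the replicate block NRC-1 gave 11 early and 16 late, and Dura3 10 early, 20 late and 37 at 0 min. These included all the probes called without it, and the replicate block changed no other count of calls. The strain comparison has no fit with the replicate block, since each course holds 1 strain. With the course as a random block (correlation 0.577) the counts were 12, 9, 17, 27 and 55, and 0 for the strain comparison.

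NRC-1 alone gave 1 late, the -1 min courses 3 early and 1 late, and the -30 min courses 11 early. Against NRC-1 replicate 3 only, the strain comparison gave 0. With the 2 courses exchanged NRC-1 late gave 1, Dura3 early 1, Dura3 at 0 min 0, the strain comparison 6, the late correlation was 0.428 and the early strain difference of HO02O14 -0.018. With no background subtraction as well, Dura3 early gave 1, Dura3 at 0 min 0, the strain comparison 3, the late correlation was 0.489 and that difference -0.16. With both courses left out NRC-1 gave 2 early and 1 late, Dura3 1 early and 1 at 0 min, the strain comparison 6, and the early correlation was 0.301. Scaled arrays gave 1 for Dura3 early and 3 for the strain comparison. Array weights gave 12 and 5 in NRC-1, 17 and 12 in Dura3, 0 for the strain comparison, and a late correlation of 0.215.

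Leaving out each course in turn gave these ranges: NRC-1 early 3 to 6, NRC-1 late 1 to 2, Dura3 early 1 to 5, Dura3 late 1 to 7, Dura3 at 0 min 0 to 9, the strain comparison 0 to 11, the late strain difference 0 to 4, and the late correlation 0.206 to 0.360. The extremes 7, 9, 4 and 0.206 came without Dura3 replicate 2, 5 without NRC-1 replicate 1, 11 without set 1 and 3 without set 2 of NRC-1 replicate 3. Where Dura3 was left with 1 course, that course was assumed to vary like the other groups.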

Other observations

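Both tests of neighbouring wells were chosen before their results were seen, after the pattern itself had been noticed. Probes whose IDs place them 2 rows apart in a plate had early NRC-1 changes that correlated at r = 0.199 over 2050 pairs (bootstrap SE 0.0267), and at 0.191 in the authors' values, while probes 1 row apart printed in 1 dip correlated at 0.0428 (SE 0.0223). Printing in the same dip is argued against as the whole cause of the NRC-1 early pattern, since pairs 2 rows apart printed in different dips correlated at 0.217 (SE 0.0425) and those printed in 1 dip at 0.185 (SE 0.0388). Place on the slide stays open: pairs side by side on the slide but 6 columns apart in the plate correlated at 0.102, and at 0.0336 in the authors' values. The pattern was not shared by all changes: wells 2 rows apart and wells side by side correlated at 0.160 and 0.0542 in NRC-1 late, 0.0988 and 0.0823 in Dura3 early, and 0.0343 and 0.169 in Dura3 late, where the order was the reverse. It was strongest in values that are not changes with copper, at 0.229 and 0.0698 in the strain difference before copper and 0.407 and 0.0252 in the mean level over the 49 samples. Genes placed in the plates by genome order, so that linked genes share their changes, may account for the NRC-1 values, but no table at hand gives the order of the probes' genes, and this was not tested.

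The 288 printed positions outside the authors' table gave signal: 90.7% of their spots in the shorter-wavelength dye and 88.2% in the longer-wavelength dye were brighter than their background. Their log2 ratios varied less over positions (median SD 0.11 per sample) than those of the table's probes (0.24). limma called 0 of them in each of the 9 comparisons, with 35 at an unadjusted p under 0.05 in NRC-1 early and 4 or fewer in each of the others. In NRC-1 early the 35 of 288 are a larger share than chance gives, and larger than the 61 of 2400 among the table's probes. These positions had no weight in the loess curve, and the cause was not tested.

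The sample of NRC-1 replicate 1 at 5 min had an r of 0.138 with its own column in the authors' table and 0.831 with that of the same course at 10 min. The 160 min change of HO02O14 in NRC-1 spread more between courses than at other times in the scanner values, from 0.76 to 2.03 (SD 0.54). In the authors' values the SD was 0.30 there and highest at 5 min, at 0.86.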
